A study of Mus musculus with 6 samples.

How the data were processed

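RNA from cultured mouse fibroblasts was measured on 1-colour (Cy3) Agilent arrays, 1 array per culture. Heart and skinned tail of male mice of 8 to 10 weeks (8 weeks in the sample labels) were digested, and the cells were plated for 5 days before RNA extraction. The series design text gives 3 biological replicates per tissue, each pooled from 2 animals, so 6 arrays were compared, 3 labelled heart fibroblasts and 3 labelled tail fibroblasts. Groups and replicate numbers came from the sample titles. Whether heart and tail cultures shared animals is not given in the sources used here. All 6 arrays lay on 1 slide, 4 in its first row (heart 1, heart 2, tail 1, tail 2) and 2 in its second row (heart 3, tail 3).

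Per the file headers, the deposited array files hold spot intensities read with Agilent Feature Extraction 11.0.1.1, which subtracted the background and corrected trends across the array but did not scale arrays to one another. The other columns used were deposited median spot and median local background intensities and flags of other kinds, 0 or 1 per spot, for signal well above background, saturation and outliers, per the file headers. A table of the whole series, deposited by the authors, lists 433 probes with a log2 fold change and a linear fold ratio of heart over tail, 261 higher in heart and 172 higher in tail. The smallest absolute fold in that table is 2.00. How the authors normalized, which arrays they averaged and how they chose these probes is not given in the sources used here.

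The main setting was fixed before the data were examined. It took log2 of the processed signal minus each array's 75th percentile over non-control probes. Outlier spots were left out, and the spots of a probe were averaged. Each array held 59305 non-control spots of 55681 probes. Probes were kept when well above background on all arrays of at least 1 group, and the probe with the highest mean stood for a gene. Probe names came from RefSeq accessions looked up in an annotation of a later mouse assembly, which named 27235 probes. A further 27 were named by symbols in the deposited table, and 28419 probes without a symbol kept the array's own name. Some of those names give mm9 coordinates, and no other coordinates are printed. The 2 groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. Python 3.11.15 with pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the plots.

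A set of 27 gene lists was also fixed beforehand, 1 of them a check of sex-linked genes. The other 26 lists, each with at least 3 tested members, were tested with camera at the preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were run beside it. Fry tests whether a list's genes move, on balance, one way, and does not compare the list with other genes. The genes named were those fixed by rule. They are the 12 largest differences in each direction among called genes with a gene symbol, groups that do not overlap and a signal well above background on all arrays of the higher group, up to 4 called members of each list with the largest differences, any tested cardiac transcription factor or Hox gene, and any tested general fibroblast marker or sex-linked gene. A gene named outside the rule is said to have been chosen after its values were seen. Since the labelled comparison called no gene, the rule was applied to the 4-array comparison.

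The 4-array comparison was added after the data were seen. It leaves out the arrays labelled heart 2 and tail 1. The first was doubted from its scanner values, and the second only from its signals set against the authors' deposited fold changes. Leaving out tail 1 thus rests on the outcome itself, and p-values of the 4-array comparison are too small by an unknown amount. No array was moved to the other group. Heart 1 and 3 were compared with tail 2 and 3 under their own labels (n = 2 per group), with the same filter applied to 4 arrays.

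For a probe not well above background on any array of the dimmer group, the fold is given as at least N. The brighter group's mean was then set against the mean, over the dimmer arrays, of the higher of the probe's own signal and the lowest signal among probes well above background. Of 20567 features tested on 4 arrays, 4554 had several tested probes. The called probes of 2 of these, Cplx2 and Rab15, disagreed in direction; both were chosen after their values were seen.

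Alternatives set beforehand were quantile, median and cyclic loess normalization, no filter or a filter on all arrays, the mean or the dimmest probe of a gene, the replicate number or the slide row as a block, an intensity trend with robust estimation, array weights, leaving out each array, the deposited table in place of the fit, other set tests, and limma's treat against a 2-fold change. Normexp background correction (offset 50) was planned on mean spot signals. That column was not used here, and the version run, on median spot signals, was chosen after the data were seen.

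The fit was tested on simulated data, with the 4-array means and spreads of 20567 features and 200 changed features. With 3 arrays against 3, it recovered 58% of features changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold. With 2 against 2 it recovered 12%, 88% and 96%. At 1.5-fold the fit recovered 10% with 3 against 3 and 2% with 2 against 2. It also called 15 and 12 unchanged features, in that order. Of 50 features changed at each fold, from 1.5-fold to 8-fold, 5, 29, 49 and 50 were recovered with 3 against 3. With 2 against 2 these were 1, 6, 44 and 48. In these single simulations the unchanged features were thus a larger share of the calls than the adjusted p threshold of 0.05. With 1 array of each group exchanged in 3 against 3, the fit recovered 0% at each of these folds. That simulation held no array with raised signal like heart 2 and no change above 8-fold. It therefore does not show why the labelled comparison called no gene. The number of arrays limits the precision, and p-values measure the spread between these cultures.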

Results

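Gene expression was compared between fibroblasts grown from the adult mouse heart and from the tail, a body wall source of ordinary fibroblasts. The series title puts the question as one of cardiogenic genes active in cardiac fibroblasts. There were 3 arrays labelled heart and 3 labelled tail. On 5 of the arrays, 47.3% to 55.2% of spots were well above background and the median processed signal lay between 24.3 and 37.8. The array labelled heart 2 stood apart, with 99.3% of spots well above background, a median signal of 949 and 2748 spots marked as non-uniform, against 0 to 7 elsewhere. Its log2 signals correlated with those of the other arrays at 0.725 to 0.748 across probes, where all other pairs lay between 0.955 and 0.988. The array labelled tail 1 correlated at 0.988 and 0.980 with heart 1 and 3, and at 0.967 and 0.955 with tail 2 and 3. No 2 arrays shared identical signals.

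Split by label, Tcf21, a transcription factor of epicardial cells and cardiac fibroblasts, averaged 4.64 higher in heart on the log2 scale (SE 3.19), and Thbs4, a matrix protein of tendon, averaged 4.96 lower (log2 difference -4.96, SE 3.65). Neither passed the test, and limma called 0 of 20197 features with 3 arrays per group. At an unadjusted p under 0.05 there were 445 features, and the smallest adjusted p was 0.275. None of the 26 tested cardiac transcription factors and 9 tested Hox genes passed (2 and 0 at an unadjusted p under 0.05). With the replicate number as a block 44 features passed, 35 higher and 9 lower, among them 3 cardiac factors. Leaving out heart 1 gave 214 features, all higher in heart, and leaving out any other single array gave 0. By label, 7 of the 25 gene lists with enough tested members were shifted by camera, 6 up in heart (cardiac transcription factors, epicardium, endothelial, leukocyte, skeletal muscle and cell cycle genes) and the tendon list down. With an estimated correlation each of the 7 had an adjusted p of 0.661, and fry called 0. The balance of directions rested on the filter, since without one 10 lists were shifted, 2 up and 8 down. Leaving out heart 1 gave 2 lists and leaving out heart 2 gave 12.

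The spread came from 2 arrays that ran against their labels. The array labelled tail 1 had Tcf21 at 5.44, next to 5.37 and 5.28 on heart 1 and 3, while tail 2 and 3 had -5.45 and -5.64. For Hoxb13, the homeobox gene of the most posterior trunk and tail, it had -6.97, next to -7.04 and -5.44 on heart 1 and 3, against 6.60 and 6.76 on tail 2 and 3. The array labelled heart 2 lay nearer to tail at these genes, with Tcf21 at -2.38 and Hoxb13 at 4.44. Over the 433 probes of the authors' deposited table, deviations from the 6-array mean correlated with the deposited log2 fold changes at 0.97 on heart 1, 0.981 on heart 3 and 0.98 on tail 1. The same correlation was -0.573 on heart 2, -0.985 on tail 2 and -0.987 on tail 3. Probes are not independent replicates, so these values carry no p.

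**Figure D1:**
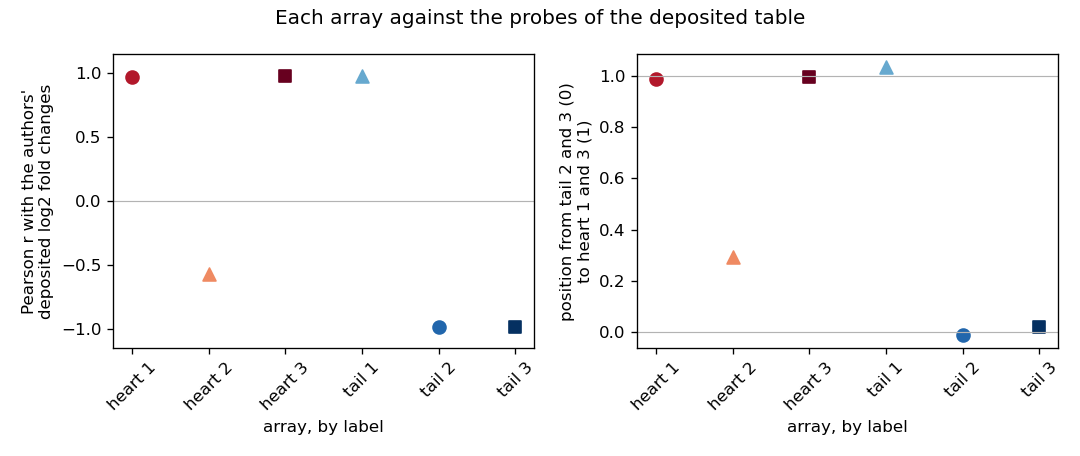
Each of the 6 arrays, by label, against the 433 probes of the authors' deposited table. The left panel gives the Pearson correlation of the array's deviations with the deposited log2 fold changes, and the right panel its place on an axis from the mean of tail 2 and 3 at 0 to that of heart 1 and 3 at 1, where the array labelled tail 1 lies at 1.03 and the array labelled heart 2 at 0.293.

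Without the arrays labelled heart 2 and tail 1, heart 1 and 3 differed from tail 2 and 3 in a broad set of developmental regulators. The cardiac regulators Tcf21, Tbx20 and Gata4 were at least 765-, 362- and 177-fold higher in heart (limma adjusted p = 0.000548, 0.00062 and 0.000624), and Hoxb13 was at least 2301-fold higher in tail (adjusted p = 0.0011). In all, 2957 of 20567 features passed, 1594 higher and 1363 lower in heart. Of these, 2425 differed at least 2-fold, 1334 higher and 1091 lower. The called features with a gene symbol numbered 2360, 1236 higher and 1124 lower. All 433 probes of the authors' deposited table had the same sign in this comparison (Pearson r 0.998 across probes), against 395 when all 6 arrays were split by label (r 0.932). Leaving out heart 2 alone, doubted from its scanner values, gave r 0.996 and 433 probes of the same sign. Leaving out tail 1 alone gave 0.977 and 428. Tail 1 was left out for running against this same table, so the match without heart 2 and tail 1 is no independent check. Removing these 2 arrays was decided after seeing the data, and for tail 1 on the outcome itself, so the adjusted p-values are optimistic. The count fell to 1902 without tail 2 and 1570 without tail 3.

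The largest differences towards heart, after Tcf21 and Tbx20, included the chloride channel accessory genes Clca3a2 (at least 338-fold) and Clca3a1, the homeobox gene Rhox5 (at least 530-fold), Art4, the growth factor Gdf6, the kinase gene Dclk3, the succinate receptor Sucnr1 and Cp, which encodes ceruloplasmin (267-fold, adjusted p = 0.000548). Aldh1a2, an enzyme of retinoic acid synthesis, was 274-fold higher (log2 difference 8.10, SE 0.28). Towards tail they included Thbs4 (log2 difference -12.13, SE 0.47, well above background on 1 of the 2 heart arrays), the Wnt antagonist Dkk2 (at least 529-fold), the carbonic anhydrase Car3 (at least 225-fold), the tendon membrane protein Tnmd (at least 175-fold) and the R-spondin receptor Lgr5 (at least 109-fold). Irx1, Ahrr, Rspo2, Hoxb9 and Hoxc13 were also among the largest on that side. Of the called features that differed at least 2-fold, the array labelled tail 1 lay nearer to heart at 2397 and nearer to tail at 28. The array labelled heart 2 lay nearer to tail at 1367 of the 2330 measured on it and nearer to heart at 963.

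Among 28 tested cardiac transcription factors, 12 rose and 4 fell in heart. Beside Tcf21, Tbx20 and Gata4, those that rose were Hand2 (at least 65.8-fold), Heyl (at least 28.2-fold), Gata6 (25.2-fold), Wt1 (at least 7.08-fold), Nkx2-5 (at least 3.86-fold), Meis1 (3.34-fold), Tbx5 (at least 3.3-fold), Tbx2 (2.25-fold) and Mef2c (at least 2.24-fold). Those that fell were Irx5, Irx3, Tbx1 and Tbx3, with log2 differences of -4.96, -3.55, -2.93 (Tbx1 was well above background on 1 of the 2 heart arrays) and -2.64. The other 12, among them Gata5 (-0.66, adjusted p = 0.163), Tbx18 (1.00, adjusted p = 0.174) and Mef2a (0.17, adjusted p = 0.674), did not pass. Leaving out 1 heart array brought calls in both directions among these 12. Without heart 3, Tbx18 (log2 difference 1.517) and Smarcd3 (0.8565) passed as higher in heart. Hey2 passed as lower in heart without heart 1 (-2.872) or heart 3 (-0.9957), and Srf as lower without heart 1 (-1.007). Hand1, Isl1 and Myocd were among those not well above background on all arrays of either group and so not tested. Adjusted over the list alone, 14 rose and 7 fell. The list as a whole was shifted up by camera (adjusted p = 0.00134; adjusted p = 0.399 with an estimated correlation), but not without heart 1 (0.0806) or with signal required on all 4 arrays (0.604). The direction by label was also up. The authors' deposited table lists 7 of these genes, all higher in heart, with log2 fold changes from 4.69 for Gata6 to 10.34 for Tcf21. Nkx2-5 lost its call without heart 1 (adjusted p = 0.0769) or heart 3 (0.076), and Tbx5 without tail 2 (0.0879). Without tail 2 or tail 3, in that order, the adjusted p was 0.112 and 0.0757 for Mef2c, 0.0613 and 0.0601 for Tbx1 and 0.111 and 0.126 for Tbx2. All calls in this list rest on leaving out the doubted arrays, since no cardiac factor passed by label. Among the called factors, the sign of Meis1 also turned by label (-0.14).

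**Figure D2:**
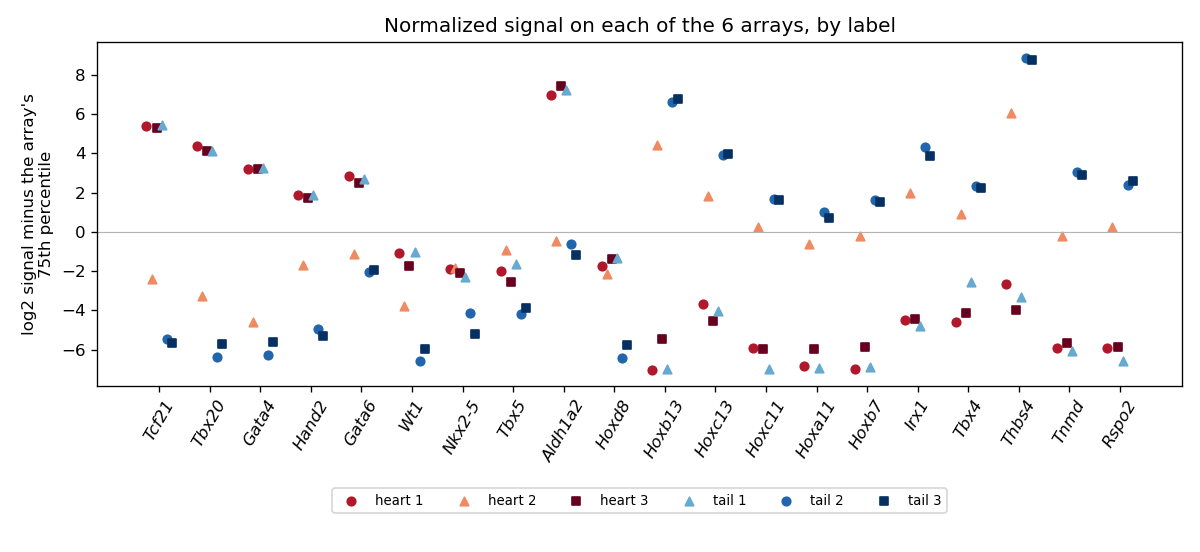
Normalized log2 signal (log2 signal minus the array's 75th percentile) of 20 named genes on each of the 6 arrays, 1 point per array, by label. At Tcf21 the array labelled tail 1 stands at 5.44 beside heart 1 and 3, and at Hoxb13 at -6.97 beside them, while the array labelled heart 2 stands at -2.38 and 4.44.

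The Hox genes, which mark position along the body axis, were lower in heart almost throughout. Of 39 on the array 24 were tested, and 21 fell while 1, Hoxd8, rose (at least 6.54-fold, adjusted p = 0.00196). In paralogue groups 9 to 13, 10 of 11 fell, among them Hoxc13 (log2 difference -8.05, SE 0.31, well above background on 1 of the 2 heart arrays), Hoxc11 (at least 70.5-fold), Hoxb9 (at least 70.6-fold) and Hoxa11 (at least 40.8-fold), and Hoxa9 did not pass (-1.05, adjusted p = 0.0535). In groups 6 to 8, 5 of 6 fell, led by Hoxb7 (at least 67.1-fold), Hoxb6 (at least 47.4-fold) and Hoxc6 (at least 35.9-fold). In groups 1 to 5, 6 of 7 fell with smaller folds, from at least 7.61-fold for Hoxb5 to 2.13-fold for Hoxb2, whose call was lost without tail 2 (adjusted p = 0.145) or tail 3 (0.18). Hoxb4 did not pass (-1.32, adjusted p = 0.105), but did without heart 1 (0.047) or heart 3 (0.0218). Adjusted over the list alone, 7 fell in groups 1 to 5, 5 in groups 6 to 8 (with 1 that rose) and 11 in groups 9 to 13. The 3 lists were shifted down by camera (adjusted p = 2.25e-06, 0.000323 and 3.97e-11; with an estimated correlation adjusted p = 0.227, 0.322 and 0.322). With signal required on all 4 arrays, 4 Hox genes passed, all lower in heart. Of all the lists 2 were then shifted down, and the limb list below was 1 of them. At most 1 of the 3 Hox lists thus kept its shift, and the others lost it or had too few tested members. The authors' deposited table lists 9 Hox genes, Hoxd8 higher in heart and 8 lower.

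Transcription factors that pattern limb and axial skeleton followed the Hox genes, with 11 of 23 lower in heart and 3 higher (16 and 3 adjusted over the list alone). Tbx4, a hindlimb regulator, was 103-fold higher in tail (well above background on 1 of the 2 heart arrays), Pax9, a sclerotome factor, at least 21.2-fold, Tbx15 28.7-fold and Dlx5 at least 15.3-fold. Tendon and ligament genes moved the same way, with 8 of 11 lower in heart and 2 higher (9 and 2 adjusted over the list alone). Beside Thbs4 and Tnmd they included Cilp (98.8-fold) and the tendon regulator Mkx (at least 15.9-fold). Both lists were shifted down by camera (adjusted p = 8.62e-06 and 7.14e-05; with an estimated correlation adjusted p = 0.227 and 0.322). With signal required on all 4 arrays the limb list kept its call (9.5e-05) and the tendon list lost it (0.0935). Smooth muscle genes went both ways, 6 lower in heart and 3 higher of 17, with the contractile genes Actg2 (44.5-fold) and Cnn1 (32.9-fold) higher in tail, and the list was not shifted by camera (adjusted p = 0.35) but lower in heart by fry (0.0481; 4 rose and 8 fell adjusted over the list alone). Of 14 skeletal muscle genes 6 fell and 0 rose, among them the embryonic myosin Myh3 (at least 16-fold) and the muscle regulator Myog (at least 2.9-fold, but adjusted p = 0.052 without heart 1). Adjusted over the list alone, 1 rose and 6 fell. That list's shift by camera (adjusted p = 0.0314; 0.602 with an estimated correlation; fry 0.0975) was lost without heart 1 (0.0538), heart 3 (0.159) or tail 3 (0.0997), without a filter (0.0637) and with signal required on all 4 arrays (0.215), and by label the list was shifted up (0.047). In the cartilage and bone list 6 of 17 fell and 3 rose (7 and 3 adjusted over the list alone). Col10a1 was at least 51.1-fold higher in tail, and Sox9 12.3-fold higher in heart. Of 14 adipocyte genes, 6 fell and 1 rose (7 and 4 adjusted over the list alone). Neither of these lists was shifted by camera (adjusted p = 0.201 and 0.101), and fry called the adipocyte list lower in heart (0.0299) and not the other (0.254). By camera both were shifted without tail 3 (0.0109 and 0.00286), the cartilage and bone list without a filter (0.00937), and the adipocyte list under median scaling (0.0271) and with the slide row as a block (0.0262). The adipocyte direction turned with signal required on all 4 arrays. The tendon, muscle, cartilage and adipocyte lists hold markers of other cells that such cultures could contain. Whether these differences lay in fibroblasts or in such cells was not tested.

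The general fibroblast markers were expressed in both tissues, and 13 of 26 did not pass. Col1a1 and Col1a2, the chains of type I collagen, differed by -0.32 and -0.25 (adjusted p = 0.35 and 0.457), and Ddr2 and Vim by 0.08 and -0.60 (adjusted p = 0.744 and 0.0718). Higher in heart were 10, among them Dpt (74.8-fold), Lum (7.72-fold), Fap (5.8-fold), Pdgfra (3.2-fold), Dcn (3.02-fold) and Col3a1 (2.42-fold). Thy1, Cd44 and S100a4 were lower in heart, by log2 differences of -1.89, -1.52 and -0.70. Adjusted over the list alone, 13 rose and 6 fell. The list was shifted up by camera (adjusted p = 0.00513; 0.652 with an estimated correlation), not by fry (0.108), and not without heart 3 (0.0847). Without tail 2 or tail 3, in that order, the adjusted p was 0.0576 and 0.0809 for Dcn, 0.121 and 0.147 for Col3a1 and 0.074 and 0.0646 for Cd44, and Pdgfra had 0.0521 without tail 3. S100a4 lost its call without any 1 of the 4 arrays (0.0579 to 0.389). By label the list as a whole ran down (median -0.67, 3 of 26 positive, adjusted p = 0.271), and the signs of Lum, Pdgfra, Dcn and Col3a1 were turned.

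Genes of the epicardium and mesothelium, the cell layer covering the heart, were mostly higher in heart, 8 of 12 against 1 lower (11 and 1 adjusted over the list alone). Beside Tcf21, Aldh1a2 and Wt1, the complement gene C3 was 38.3-fold higher, and the keratin gene Krt19 went the other way (log2 difference -5.25, SE 0.44, well above background on 1 of the 2 heart arrays). Tcf21 and Wt1 also stand in the list of cardiac factors. Whether these genes and the other cardiac factors differed in fibroblasts or in other cells of the cultures was not tested. The list was shifted up (camera adjusted p = 3.1e-08; 0.227 with an estimated correlation). Cardiomyocyte genes were not shifted by camera (adjusted p = 0.0833; 0.00483 without tail 2) or fry (0.108), though lower in heart under quantile (0.0475), median (0.03) and loess (0.0431) normalization, with the mean (0.0445) or the dimmest probe (0.0341) of a gene and with the slide row as a block (0.0228); adjusted over the list alone, 2 rose and 5 fell. Tnnt2 (19.1-fold) and Myl4 (5.21-fold) were higher in heart, and Actc1 (at least 29.9-fold) and Mb (at least 4.24-fold) were among 4 genes higher in tail. The call of Mb was lost without heart 3 (0.0571).

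Markers of other cells also rose with heart. Of 17 endothelial genes 14 rose and 0 fell (14 adjusted over the list alone), among them Cldn5 (at least 9.95-fold), Robo4 (at least 16.2-fold), Icam2 (9.09-fold) and Tie1 (at least 1.91-fold). Of 23 leukocyte and macrophage genes 14 rose and 0 fell (19 adjusted over the list alone), among them Ms4a7 (32.8-fold), Aif1 (23.7-fold), Cx3cr1 (11.6-fold) and Cd52 (9.57-fold). Both lists had a median log2 difference near 1.9 (1.92 and 1.91) and were shifted up by camera (adjusted p = 9.47e-10 and 2.65e-10; with an estimated correlation adjusted p = 0.227 and 0.554). Under normexp both medians were smaller, above all that of the endothelial list. Fry called the endothelial list (adjusted p = 0.00646) and not the leukocyte list (0.0721). Icam2 lost its call without heart 3 (adjusted p = 0.0597), and Cx3cr1 without heart 3 (0.0546) or tail 3 (0.0587).

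Genes of secreted signals went both ways. In the Wnt list 15 of 27 fell in heart and 5 rose (16 and 8 adjusted over the list alone), with Dkk2, Lgr5 and the R-spondin Rspo2 (at least 126-fold) higher in tail and the antagonist Frzb 73.5-fold higher in heart. The list was shifted down (camera adjusted p = 0.00771; 0.399 with an estimated correlation), but not with signal required on all 4 arrays (0.555). In the BMP and TGF-beta list 13 of 37 fell and 7 rose (16 and 9 adjusted over the list alone), with the antagonists Grem1 (at least 32.3-fold) and Chrdl1 (102-fold, well above background on 1 of the 2 heart arrays) higher in tail and Gdf6 337-fold higher in heart (well above background on 1 of the 2 tail arrays). That list was not shifted by camera (adjusted p = 0.265), but fry called it lower in heart (0.0146). In the FGF, PDGF and IGF list 10 of 33 fell and 6 rose (13 and 14 adjusted over the list alone), with Fgf5 (at least 40.3-fold), Pdgfc (23.5-fold), Igfbp6 (16.6-fold) and Fgf10 (at least 11.4-fold) higher in tail. Its median (-0.06) and mean (-0.35) were negative while camera ranked it up, without a call (adjusted p = 0.884), and that direction was down under quantile, median and loess normalization. Matrix proteases and their inhibitors had 3 of 22 higher and 0 lower (5 and 0 adjusted over the list alone), the stromelysin Mmp3 (208-fold), Mmp8 (at least 23.1-fold) and the inhibitor Reck (1.71-fold), and the list was shifted up (adjusted p = 0.00326; 0.51 with an estimated correlation) but not without heart 3 (0.106). The call of Reck was lost without heart 3 (0.051), tail 2 (0.297) or tail 3 (0.327), and its sign turned by label (-0.53).

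**Figure D3:**
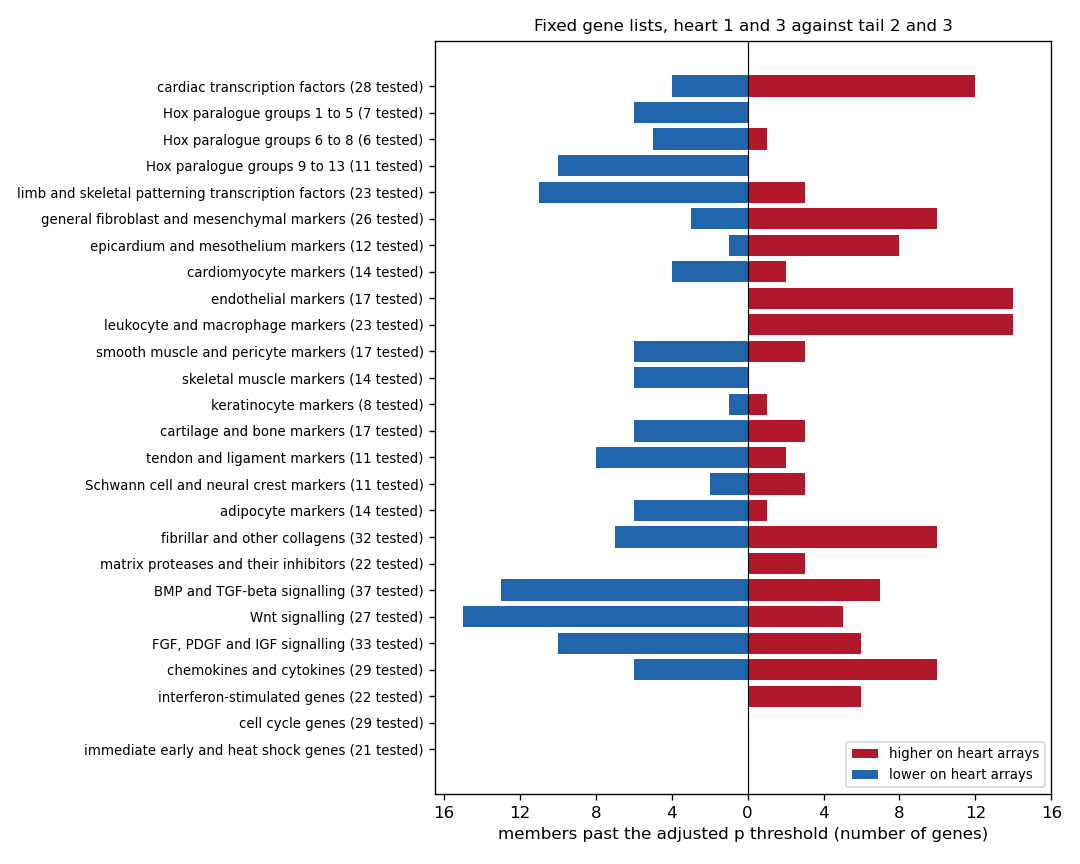
Number of members of each fixed gene list past the adjusted p threshold in the comparison of heart 1 and 3 with tail 2 and 3, with higher in heart to the right and lower in heart to the left. The longest bars are 14 endothelial and 14 leukocyte genes higher in heart, and 15 Wnt genes and 13 BMP and TGF-beta genes lower in heart.

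Of the Y-linked check genes, Ddx3y and Eif2s3y were well above background on all 4 arrays and did not differ (log2 differences 0.0009 and 0.12, adjusted p = 0.998 and 0.643), nor did Uty (-0.87, SE 1.19). Xist and Kdm5d were not well above background on all arrays of either group. Each row of the slide holds 1 of the 2 heart and 1 of the 2 tail arrays, and the 2 rows' differences correlated at 0.837 across all tested features, which are not independent replicates. With the slide row as a block, 2929 features passed.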

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

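The tests on heart 2 in this part were chosen after the result was seen. The dimmest spike-in control, a synthetic RNA outside the comparison, had a median signal of 620 on the array labelled heart 2, against 4.36 to 8.31 on the other 5 arrays and 7.48 at that array's own negative control probes. Light between the spots is argued against, since the local background rose by 8.00 signal units and the median spot signal by 834. A higher scanner gain or labelling yield is argued against too, since the brightest spike-in stood at 0.96 times the mean of the other arrays while the dimmest stood at 105 times. Labelled material bound to probes of any sequence would raise the dimmest spike-in and the negative controls alike. The spike-in rose, but the negative controls, at 7.48, lay within the range of the other arrays (4.26 to 8.12). That prediction was met only in part, and such binding cannot be told apart from a cause tied to probe sequence. No biological explanation was tested, and groups of 3 arrays were not tested for outliers.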

How the results depend on the processing

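The comparison of heart 1 and 3 with tail 2 and 3, and all alternatives to it, were chosen only after the results were seen, and so was normexp on median signals; the other alternatives to the labelled comparison were planned. Features here are gene symbols or, where a probe has none, the array's own names. By label, 0 features passed under each other scaling, filter, probe choice, variance model and the slide row as a block, except under array weights (1 feature, also at 2-fold) and the replicate number as a block (44 features, 44 at 2-fold, 3 cardiac factors). Deviations of cultures of equal number from their labelled group means correlated at 0.195, 0.259 and -0.33 for numbers 1, 2 and 3. The doubted arrays weigh on those means, so whether equal numbers pair could not be told. Leaving out 1 array gave 0 to 214 features (0 to 214 at 2-fold), 2 to 12 lists and correlations with the deposited table of 0.7932 to 0.9958. That correlation was 0.8809 under normexp, 0.5194 within the first slide row and 0.9949 within the second. Lists numbered 4 under quantile normalization and 0 with an estimated correlation or fry. The median of all genes by label was -0.40, against -1.33, -0.29, -0.01 and -0.37 under median, quantile, loess and normexp. Without heart 2 and tail 1 there were 2957 features, 2425 at 2-fold, 16 lists, 16 cardiac factors, 22 Hox genes and a correlation of 0.9978. The deposited table lists 408 features, 408 at 2-fold, 7 cardiac factors and 9 Hox genes, for both comparisons.

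On 4 arrays, other scalings and normexp gave 2873 to 3003 features, with a correlation of 0.9421 under normexp. Without a filter 716 features passed (716 at 2-fold) with 9 cardiac factors. With signal required on all arrays there were 1608 at 2-fold, 9 lists, 5 cardiac factors and 4 Hox genes, since genes absent from 1 tissue were no longer tested. Lists numbered 0 with an estimated correlation and 13 by fry (4 up and 9 down, against 9 and 7 by camera), and treat gave 1045 features. Leaving out 1 array gave 1570 to 3951 features (1570 to 3236 at 2-fold), the lone array of a group being assumed to vary like the other group. Of the named genes that were also tested by label, 29 passed in neither comparison, whether or not their sign turned. A further 79 kept direction but no longer passed by label. The other 10 had passed on 4 arrays and turned sign by label: Lum (-0.05418), Reck (-0.531), Oas2 (-0.2203), Meis1 (-0.1361), Col3a1 (-0.3568), Dcn (-0.4243), Eng (-0.2395), Loxl1 (-0.474), P4ha1 (-0.1945) and Pdgfra (-0.262). Beyond these stated constructions the cause was not tested. Signal over background tells little on heart 2, where 99.3% of spots passed. No replicate block was run on 4 arrays, which share only number 3.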

Other observations

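The 4-array comparison, the tests on the arrays labelled heart 2 and tail 1, the other splits of the arrays, normexp on median signals and the test against genes of like brightness were chosen only after the results were seen. Fibrillar and other collagens divided by chain. Of 32 tested, 10 rose and 7 fell in heart (11 and 12 adjusted over the list alone), Col4a6 by 16.5-fold, while Col8a2 was 19.7-fold and Col22a1 at least 2.84-fold higher in tail, and the list was not shifted (camera adjusted p = 0.596; its median was -0.19 and its mean 0.01). Among 29 chemokines and cytokines 10 rose and 6 fell (11 and 6 adjusted over the list alone). Il33, an alarmin, was 72.9-fold, Ccl6 19.5-fold and Ccl17 16.6-fold higher in heart, Il33 and Ccl17 being well above background on 1 of the 2 tail arrays, and Cxcl9 was at least 6.67-fold higher in tail. The list was shifted up by camera (adjusted p = 0.0218; 0.554 with an estimated correlation; fry 0.0975), but not without heart 3 (0.164) or with signal required on all 4 arrays (0.221). Of 22 interferon-stimulated genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), among them Rsad2 (5.72-fold), Cmpk2 (5.11-fold) and Oasl1 (3.9-fold), with a list shift at adjusted p = 1.13e-05 (0.602 with an estimated correlation; fry 0.12). By label that list ran down (median -0.94, 3 of 22 positive, adjusted p = 0.365). On the same arrays 14 of 23 leukocyte and macrophage markers rose, at a list median of 1.91, and these rises were not separated from it. Oasl1 lost its call without tail 3 (adjusted p = 0.0586), and Cxcl9 without tail 2 (0.0533) or tail 3 (0.0785).

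None of 29 cell cycle genes passed in limma, over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05), and 28 lay higher in heart, at a median log2 difference of 0.84, which was 0.16 without heart 1 and 1.53 without heart 3. The list was shifted up (adjusted p = 0.0004; 0.661 with an estimated correlation of 0.992; fry 0.437) but not without heart 1 (0.212). None of 21 immediate early and heat shock genes passed (6 at an unadjusted p under 0.05), and that list was not shifted (adjusted p = 0.78), except without heart 1 (0.00473). Of 11 Schwann cell and neural crest genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), Ngfr by 16.8-fold towards heart and S100b by 6.73-fold towards tail, and of 8 keratinocyte genes 1 rose (Perp, 2.1-fold) and 1 fell (Dsp, at least 6.88-fold), as when adjusted over the list alone. Neither list was shifted (adjusted p = 0.78 for each), and the median of the Schwann list (-0.22) was opposite in sign to its mean (0.29) and to the test, whose direction turned under normexp. Perp, well above background on 1 of the 2 tail arrays, lost its call without any 1 of the 4 arrays (adjusted p 0.0653 to 0.287), and Ngfr without tail 2 (0.0797) or tail 3 (0.0546). Among 2276 unnamed transcribed regions, 93 rose and 93 fell. The largest difference, chosen after its values were seen, lay on mm9 chromosome 7 from 91558475 to 91733625, at a log2 difference of -9.26 (SE 0.52, well above background on 1 of the 2 heart arrays).

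The arrays labelled heart 2 and tail 1 ran against their labels. A mixed culture behind tail 1 is argued against, since probes the authors' deposited table lists as higher in tail lay at a median log2 of -0.0761 from heart 1 and 3 on it (SD 0.37 over 172 probes), where tail 2 and 3 lay 2.95 above heart. The raised signal of heart 2 as the whole cause of its profile is argued against, since 96 of 96 bright heart-high probes lay below equally bright other probes on it, by a median log2 of -1.97. Both tests rest on probes the authors chose, and which arrays they averaged is not given. If they set heart 2 with tail, or tail 1 with heart, that choice of probes favoured these outcomes. Correlations over all probes do not use that choice. In them tail 1 stood at 0.988 and 0.980 with heart 1 and 3, against 0.967 and 0.955 with tail 2 and 3. An exchange of the labels of these 2 arrays remains a candidate explanation, with tail 1 at 1.03 on the axis from tail 2 and 3 (0) to heart 1 and 3 (1), and a tail sample hybridised poorly or a different sample on heart 2 stays open. Which label is wrong, and whether the files or the samples changed place, was not tested.

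The split by label called 0 features, so all 10 splits of the 6 arrays into 3 and 3 call at least as many by construction, and counting them tests nothing; the highest other called 943. Apart from this, with 10 splits no share under 0.05 can be had. The split with 943 sets heart 1, heart 3 and tail 1 against heart 2, tail 2 and tail 3, which is the grouping already seen against the deposited table. Its count points to a structure of the samples, but restates that observation and is no independent evidence for it.

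For the higher endothelial and leukocyte markers on heart 1 and 3, a shift of all genes of like brightness between arrays is argued against as the whole cause, since the listed genes lay a median of 1.85 (endothelial, SD 1.41, 16 of 17 above) and 1.97 (leukocyte, SD 1.33, 22 of 23 above) over other genes of like mean signal. Other scalings decide nothing, as they moved the median of all genes by 0.0647 at most and the list medians were 1.90 or more under each, but under normexp, a background correction, these fell to 1.00 (endothelial) and 1.64 (leukocyte), so the size of the endothelial difference depends on how dim signals are treated. More endothelial cells and leukocytes in the heart cultures may account for it, since 34 tested further markers of these cells, none of them in the fixed lists, had a median log2 difference of 1.83, with 19 of 20 leukocyte markers higher, 11 of them past the threshold (Lgmn, the brightest of the 20, ran the other way without passing, by -0.38). Of 14 endothelial markers 9 passed as higher and 2 as lower, Cd34 (-1.60) and Clec14a (-4.63), which more endothelial cells alone would not lower (genes chosen after their values were seen). A difference between heart and tail fibroblasts themselves stays open, as untested, and the labels name no sorting of the cultures.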
